A study of Thermoplasma acidophilum DSM 1728 with 6 samples.

How the data were processed

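RNA was measured in 6 cultures of the archaeon Thermoplasma acidophilum DSM 1728, 3 grown with air and 3 grown without oxygen. Per the labels' protocols, total RNA was extracted with a bacterial RNA kit, checked on a bioanalyzer, labelled with Cy3 by the array maker and hybridised to a 1-colour NimbleGen array of 60-mer probes, 1 array per culture. Each array carried 1482 protein-coding sequences, here called features. The files show 20 probes per feature and 5 spots per probe on each array, so 148200 gene spots, and 45338 spots of 20000 probes of random sequence.

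The deposited spot files hold the intensity of each spot on a linear scale, neither background-corrected nor normalized, as extracted with NimbleScan 2.4.31 per the file headers. The mismatch column is 0 throughout and was not used. A second deposited table holds 7410 values per array, 1 for each feature in each of the 5 on-chip blocks, also on a linear intensity scale. The submitters' processing notes name RMA for these values, and the series' design text names the ArrayStar software. Whether the 2 groups were normalized together is not given in the sources used here. The column medians of that table were 5851 to 6024 in the aerobic arrays and 4212 to 4291 in the anaerobic arrays, and its values correlated with the recomputed ones across features within each array at r of at least 0.99, in the same direction. Their log2 medians differed by -0.49 between the groups (anaerobic minus aerobic), with SDs of 0.02 and 0.01 within them. Quantile normalization of all 6 arrays together, run on the spot files, left a difference of 0.07 between the feature medians, and normalization of each group apart left -0.87. The deposited table was thus not quantile-normalized over all 6 arrays together. How its groups were scaled to each other stays unknown, and it served only as an alternative.

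The spot intensities were processed anew in R 4.3.3 with limma 3.58.1, following the steps of RMA. Background was corrected on all spots with normexp and an offset of 50, and random-sequence spots were then left out. Gene spots were quantile-normalized between the 6 arrays and log2-transformed. The 5 spots of a probe were averaged, and the 20 probes of a feature were combined by median polish. Groups were compared with lmFit and eBayes on these log2 values, 3 arrays against 3 with no covariate. A two-sided p adjusted by Benjamini-Hochberg over all 1482 features was called at a threshold of 0.05, alone and together with a change of at least 2-fold. Every adjusted p printed comes from this limma test, unless another test is named with it. A quantile-normalized change is relative to the whole distribution of gene signals on the array.

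A feature counted as above background on an array where the median of its probes exceeded the 95th percentile of the random-sequence spots of that array. The number of arrays limits the precision of every comparison. The median standard deviation (SD) of a feature between replicate arrays was 0.07 in the aerobic and 0.08 in the anaerobic group on the log2 scale, and the median SD between the 5 blocks of 1 array was 0.03. The labels state that each array came from a separate culture.

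The pipeline was tested on simulated arrays built from the probe means of the aerobic arrays and the observed within-group spread of each feature. The noise of single spots, the background noise and the scale of each array were set to chosen sizes. Changes were given to 200 of the 1482 features. Of 50 features each, it recovered 25 at a log2 change of 0.25, 47 at 0.5, 50 at 1 and 50 at 2, and it called 15 of 1282 unchanged features. The median estimate for a true log2 change of 2 was 1.91. These rates need not hold for the real comparison. The simulation left most features unchanged and gave both groups like signal distributions. On the real arrays most features passed the test and the distributions differed between the groups.

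Replicate numbers are shared by the groups, but each culture was separate. The deviations of same-numbered arrays from their group means correlated at 0.12, 0.18 and -0.12, so the numbers were not treated as pairs. File headers give 3 scanning days. All anaerobic arrays were scanned on the first, aerobic replicates 1 and 2 on the second and aerobic replicate 3 on the third. Scanning and group can therefore not be told apart.

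Before the data were examined, the test, the thresholds, the rule for the features named and most alternatives were fixed. The rule took the 8 highest and the 8 lowest changes among features past the test with no overlap between the groups. The files pair no gene name with a feature, no annotation was used here, and a feature's place in the numbering was not used to name it. For that reason 27 gene lists fixed by product name, and the tests planned on them, were not run, and only the 2 highest and the 2 lowest features are given by their design ID. Alternatives covered the background correction, the normalization, the summary of probes, the deposited values, a filter on dim features, the variance model, the replicate number as a block, the scanning day as a random block, the thresholds and leaving out each array. Another 4 were chosen after seeing the data: the first or last 10 probes only, the deposited values centred on their median, and leaving out features with a spot at the scanner ceiling.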

Results

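Gene expression was measured in Thermoplasma acidophilum, a wall-less archaeon that lives in hot, acidic settings and can grow with oxygen or, when sulfur is present, without it. The arrays compared 3 cultures grown with air and 3 grown without oxygen, all at 59 °C and all harvested in the late-exponential phase. Several conditions changed together with oxygen. The aerobic medium had a pH of 1.6 and was shaken at 120 rpm for 2 days. The anaerobic medium had a pH of 2.0, contained 0.4% (w/v) elemental sulfur and 1.2 g/l of sodium sulfide, and was stirred at 300 rpm for 4 days under 80% nitrogen and 20% carbon dioxide. Each of the 1482 features of the array stands for 1 protein-coding sequence of the genome. The files identify features by design numbers only, so that no gene, pathway or genomic position could be named.

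Nearly all features gave signal in both cultures. Of the 1482 features, 1472 were above the random-sequence background on all 6 arrays. All features were above it on all 3 aerobic arrays, whereas 4 were above it on no anaerobic array and 6 on only 1 or 2 of them. Of these 4, 1 was lower in the anaerobic cultures, by at least 1.18-fold (adjusted p = 0.00044), and for the other 3 no fold can be given. Of those 3, 2 passed the test as higher in the anaerobic cultures and stand among the counts given below, although no anaerobic array read them above background. The raw signal of gene spots was lower on the anaerobic arrays. Their median intensity was 6000, 5746 and 6933 on aerobic replicates 1 to 3, and 3245, 3537 and 2976 on anaerobic replicates 1 to 3. The log2 medians differed by -0.94 (anaerobic minus aerobic), against SDs of 0.14 and 0.12 (n = 3 each; exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 can give). Random-sequence spots had medians of 140 to 172 on the aerobic and 169 to 215 on the anaerobic arrays (log2 difference 0.26, SDs 0.16 and 0.17, n = 3 each; exact permutation p = 0.2). Between 8 and 373 of the 148200 gene spots per array reached the scanner ceiling of 65535. These spots belonged to 75 features, whose changes may be understated.

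**Figure D1:**
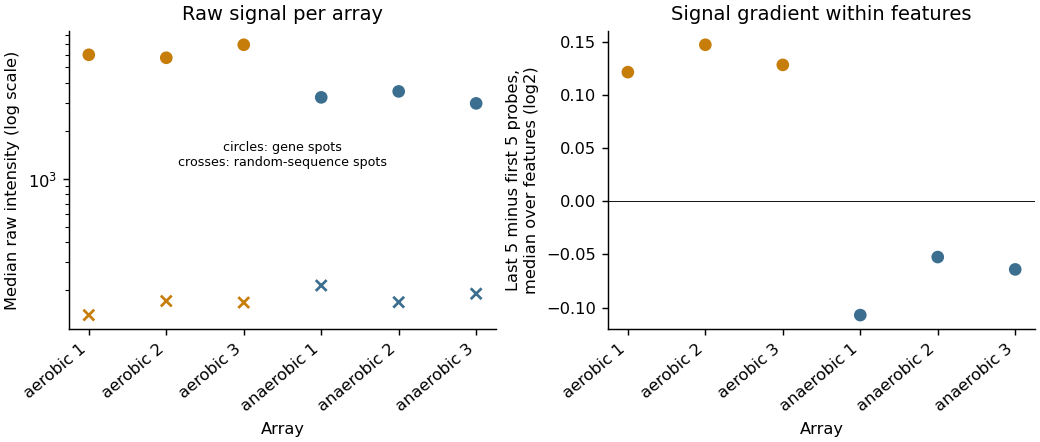
Left, median raw intensity (log axis) of gene spots (circles) and of random-sequence spots (crosses) on each array; right, median over the 1482 features of the mean log2 signal of the last 5 probes minus that of the first 5 probes. Aerobic arrays are orange and anaerobic arrays blue; gene spots were dimmer on the 3 anaerobic arrays, and the gradient was above 0 on the aerobic and below 0 on the anaerobic arrays.

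A gradient of signal along the features also moved with the group. In the aerobic arrays the last 5 probes of a feature, by their listed position, were brighter than the first 5 by a median of 0.13 ± 0.01 on the log2 scale (SD, n = 3). In the anaerobic arrays they were dimmer, with a median of -0.07 ± 0.03 (SD, n = 3). The groups differed by -0.21 (exact two-sided permutation test, p = 0.1, the smallest possible).

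The main comparison asked which genes were expressed differently in anaerobic and aerobic cultures. Most features differed between the groups, whose arrays were also scanned on different days. After normalization, 1186 of 1482 features (80.0%) passed the test, 599 higher and 587 lower in the anaerobic cultures, and 296 did not pass. At least 2-fold changes were seen in 329 features (22.2%), of which 178 were higher and 151 lower. In 55 features the change was at least 4-fold (23 higher and 32 lower), and in 23 it was at least 8-fold (8 higher and 15 lower). The changes exceeded the spread between cultures. Log2 fold changes had an SD of 0.98 over features and a median size of 0.51, against a median standard error (SE) of 0.07. This SE rests on the spread within groups only, so it leaves out any effect of the array run. Arrays of 1 group correlated across features at 0.995 to 0.998, and arrays of different groups at 0.854 to 0.858. Principal component 1, which separated the groups, held 96.8% of the variance.

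Each of the 329 features that changed at least 2-fold had no overlap between the 3 aerobic and the 3 anaerobic values. Over all features this held for 1232 (83.1%), where chance gives 10%. In 319 of the 329 all 20 probes moved in the direction of the feature, and in the others 19 did. Among features that did not pass the test, a median of 13 of 20 probes had the feature's sign.

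These directions are relative to the distribution of signals on each array. The arrays were also scaled to their random-sequence spots, taken after background correction. The median feature was then lower by 0.96 on the log2 scale in the anaerobic cultures. At this scaling 32 features were at least 2-fold higher and 714 lower. The shift is near the raw log2 difference of -0.94 between the gene-spot medians. Random-sequence spots measure background, so scaling to them does not remove a difference in RNA amount or labelling. It therefore does not show that most genes were lower. In the authors' deposited values, taken as they stand, 105 were at least 2-fold higher and 340 lower, and the median feature was lower by 0.37. Those values were level within each group but not between the groups, and centred on the median of each array they gave 244 higher and 164 lower. All anaerobic arrays were scanned on another day than the aerobic ones, so an effect of the array run cannot be told apart from one of the cultures.

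The strongest decrease was that of feature TI273075S001356. Its log2 intensity fell from 14.89 ± 0.09 in the aerobic to 8.81 ± 0.02 in the anaerobic cultures (SD, n = 3 each), a 67.5-fold decrease (log2 change -6.08, SE 0.06, limma adjusted p = 4.4e-12). By signal it ranked 97 of 1482 with air and 1412 without. Feature TI273075S000788 fell from 14.48 ± 0.28 to 8.81 ± 0.08 (SD, n = 3 each), a 51.0-fold decrease (log2 change -5.67, SE 0.12, adjusted p = 3.2e-10), and its rank moved from 153 to 1414. Both fell under every scaling, with log2 changes of -7.25 and -6.89 when the arrays were scaled to random-sequence spots. The 8 features with the strongest decreases all fell at least 14.8-fold, and 6 of them carried consecutive design numbers. All 8 were among the brightest 159 features with air and above background on all arrays.

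The strongest increase was that of feature TI273075S000621, from 8.09 ± 0.04 to 12.98 ± 0.07 (SD, n = 3 each). This is a 29.7-fold increase (log2 change 4.89, SE 0.06, adjusted p = 1.2e-11), with a move in rank from 1461 to 534. Feature TI273075S000622 rose 26.1-fold, from 9.79 ± 0.09 to 14.49 ± 0.02 (SD, n = 3 each; log2 change 4.70, SE 0.06, adjusted p = 1.7e-11), and its rank moved from 1301 to 158. Both rose under every scaling, with log2 changes of 3.94 and 3.83 when the arrays were scaled to random-sequence spots. The 8 strongest increases were at least 8.66-fold, and 4 of these features carried consecutive design numbers. In the third and the sixth of them the anaerobic arrays differed more than elsewhere (SDs of 0.58 and 0.53), with replicate 2 the lowest.

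**Figure D2:**
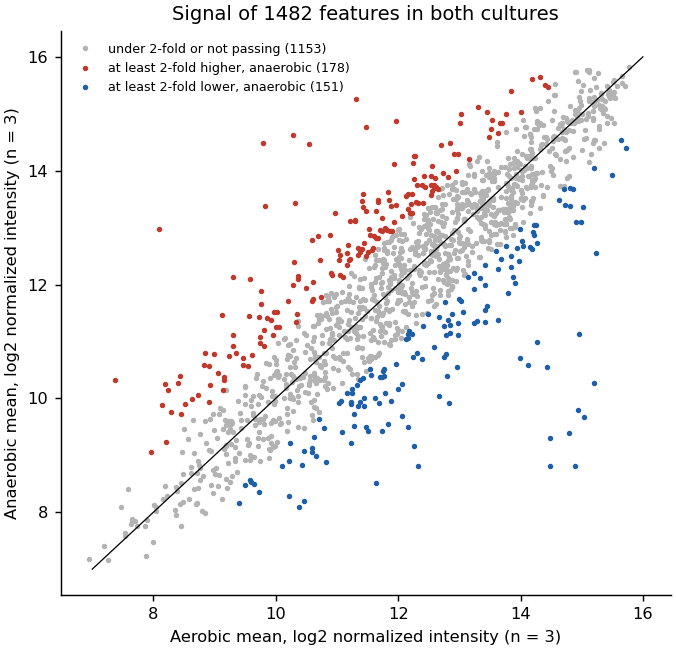
Mean normalized log2 intensity of each of the 1482 features in the 3 anaerobic arrays against that in the 3 aerobic arrays; the line marks equal signal. Features that changed at least 2-fold are red (178 higher in anaerobic cultures) and blue (151 lower), and the others are grey.

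The brightest features were partly the same in both cultures. Of the 100 brightest of each group, 70 were common to both; how bright a feature is depends on its probes as well as on its RNA. Of the 100 brightest aerobic features, 13 were at least 2-fold lower in the anaerobic cultures. Likewise, 13 of the 100 brightest anaerobic features were at least 2-fold higher there. Each set was chosen by its signal in that group, which favours these directions. Over all 1482 features, 151 were at least 2-fold lower and 178 higher. The features were also split into 4 groups of like size by mean signal. In the dimmest group 98 of 371 features changed at least 2-fold (51 higher and 47 lower), and in the next groups 96 of 370 (48 and 48) and 91 of 370 (55 and 36) did. In the brightest group 44 of 371 changed (24 and 20). The SD of the log2 fold changes was 0.65 in the brightest group and 0.98 to 1.12 in the other groups. This split used the mean over both cultures, and the brightest group starts at a mean of 13.4. A feature that is dim in 1 culture therefore tends to be left out of it. The smaller changes in that group thus do not show that highly expressed genes change less.

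**Figure D3:**
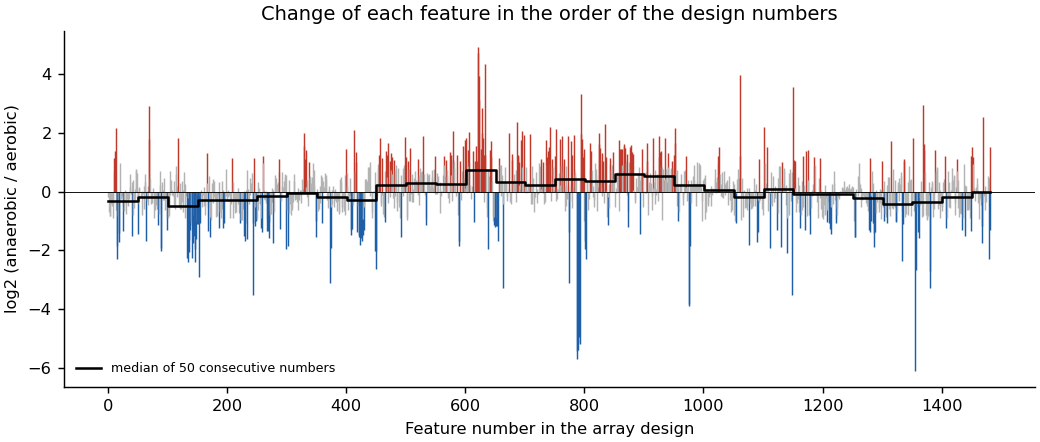
Log2 fold change (anaerobic over aerobic, n = 3 each) of the 1482 features, drawn as vertical lines in the order of their design numbers. Features that changed at least 2-fold are red (higher) or blue (lower), and the black line is the median of each 50 consecutive numbers, which was above 0 in all 12 such bins from number 451 to 1050.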

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

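The random-sequence probes, which the comparisons above use only to set the background and, in 1 alternative, the scale, held a small number of probes with signal. Of 20000 such probes, 6 exceeded 3 times the median of the random-sequence spots in every one of their 2 or 3 spots on all 6 arrays, at 3.39 to 12.1 times that median. The brightest reached 10.6 ± 1.31 times the median in the aerobic and 11.5 ± 0.61 times in the anaerobic arrays (SD, n = 3 each). Another was at 7.56 ± 1.19 times with air and 4.63 ± 0.40 times without. This criterion was chosen after seeing the data.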

How the results depend on the processing

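The number of features that passed the test stayed within 1.5 times the reported 1186 under every alternative (1062 to 1292), and leaving out 1 array at a time gave 1064 to 1140, or 312 to 339 at least 2-fold. As the array holds 1482 features, the upper side of that limit could not be passed. A like count also does not show that the same features were called in the same direction. The split between higher and lower depended on the scaling. Centred on random-sequence probes, 117 features passed as higher and 1158 as lower, and 746 changed at least 2-fold (32 higher and 714 lower), as follows from the shift of the median feature by -0.96. Of the 329 features reported at least 2-fold changed, 183 were then still called in the same direction and 26 turned their sign. At this scaling the limma adjusted p of TI273075S000621 was 1.95e-145, against 1.2e-11 as reported. Such a value cannot rest on the spread of 1 feature over 6 arrays. The counts past the test at this scaling are therefore not comparable with those of the other settings. With the authors' deposited values, 389 passed as higher and 903 as lower, and the 2-fold calls were 105 higher and 340 lower; 246 of the 329 features reported at least 2-fold changed were still called and none turned its sign, with the median feature shifted by -0.37. Their column medians differed between the groups by -0.49 on the log2 scale, against SDs of 0.02 and 0.01 within groups, where joint quantile normalization of the 6 arrays left 0.07, so these values were not normalized that way; centred on the median, the same values gave 244 higher and 164 lower. By construction, stricter limits on the size gave fewer features: 55 at 4-fold (23 higher and 32 lower), and 219 with a test against 2-fold (limma's treat), of which 110 were higher. The last 10 probes alone gave 147 higher and 189 lower at 2-fold, and the first 10 gave 217 and 136. With the replicate number as a block 1179 features passed; only the numbers are shared, and the deviations of same-numbered arrays correlated at -0.12 to 0.18. With the scanning day as a random block 1202 passed, but no day held arrays of both groups, so this cannot remove an effect of the day from the comparison. The filter on dim features removed none of the 1482 and so tests nothing. The 4 features given by ID kept their direction and passed under every alternative run on them, which leaves out the stricter thresholds. Both analyses along the design numbers, chosen after seeing the data, passed under every alternative that can change them (the variance models, the replicate block, the filter on dim features and the centring of the deposited values cannot), with a correlation of adjacent features of 0.48 to 0.51 and a wave of 0.35 to 0.43. The tests planned on gene lists were not run, for want of names. Signal over background limits the folds of the 10 features not above it on every anaerobic array, and the background correction also moved others: 310 features changed at least 2-fold with none and 346 with an offset of 0.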

Other observations

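The analyses of neighbours, of the broad order along the numbers and of short features were chosen after seeing the data. So was the test of a drift. The probe gradient, the split by mean signal and the overlap of the brightest features were also not among the analyses fixed beforehand. The other tests of explanations were set before their own results were seen. Features with adjacent design numbers changed together. The log2 fold changes of adjacent features correlated at 0.49 across features (bootstrap SE 0.03; features are not independent replicates), and the correlation was 0.27 at a distance of 2 numbers, 0.19 at 3 and 0.09 at 5. In 10000 shuffles of the numbers the highest was 0.10 (one-sided permutation p = 0.0001, the smallest they can give). Runs of at least 3 consecutive numbers that all changed at least 2-fold in 1 direction numbered 32 and held 118 features, against a mean of 3.61 runs and a maximum of 12 in the shuffles (permutation p = 0.0001). In all, 18 runs with 67 features were higher and 14 runs with 51 features were lower in the anaerobic cultures. The longest run held 6 features. In the shuffles the longest run held 3.31 features on average and 7 at most (one-sided permutation p = 0.0039).

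The strongest run was lower. Its 6 features fell by log2 changes between -5.67 and -4.93, a median of 38.7-fold, and it was followed in size by a run of 3 that fell by a median of 14.2-fold. Another run of 6 features rose by a median of 11.4-fold, with log2 changes of 1.03 to 4.89, and a further run of 6 rose by a median of 3.05-fold. All features of the 32 runs were above background on all arrays. Scaled to random-sequence spots, where the median feature fell by 0.96, 91 runs were counted. This count was not set against shuffles. With 714 features at least 2-fold lower at that scaling, runs by chance are more frequent, so it cannot be compared with the 32.

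The place of spots on the chip does not account for the likeness of neighbours, since the mean distance between spots of adjacent features was 1.0003 times that of random pairs. With the middle 10 probes of each feature only, the correlation was still 0.47, which argues against sequence shared at the ends of features. A slow drift along the numbers is argued against as the whole cause by the correlation of 0.11 at a distance of 10, and with the mean of each 50 numbers removed adjacent features still correlated at 0.43. A candidate explanation is that the numbers follow the genome and that neighbours are transcribed together, but no positions were used here and this was not tested. Near-identical sequences with adjacent numbers also stay open.

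Higher and lower features also lay in different broad stretches of the numbering. Of bins of 50 consecutive numbers, all 12 from number 451 to 1050 had a median log2 fold change above 0. These 600 features had a median of 0.33, and 127 of them were at least 2-fold higher in the anaerobic cultures and 33 lower. The other 882 had a median of -0.19, with 51 higher and 118 lower. This stretch was chosen for its values, so its counts carry no test. A single wave that closes on itself over the 1482 numbers had an amplitude of 0.38 on the log2 scale (SD 0.04 over random subsets of features) and its peak at number 764. Scaled to random-sequence spots, where the median feature fell by 0.96, the amplitude was 0.35. Within groups the waves were smaller. Aerobic replicate 3, the single aerobic array scanned on another day, differed from aerobic replicates 1 and 2 by amplitudes of 0.072 and 0.064, and arrays of 1 group scanned on the same day differed by 0.0054 to 0.011. Over 30 bins of up to 50 numbers, the differences of aerobic replicate 3 from replicates 1 and 2 correlated negatively with the change between the groups, taken from arrays not used in them, with r of -0.67 and -0.62 (two-sided permutation p over circular shifts of the bins 0.1 and 0.233). The differences of anaerobic replicates 2 and 3 from replicate 1, with amplitudes of 0.0072 and 0.0096, gave r of -0.31 and -0.42 (permutation p = 0.0333 each, the smallest that 30 shifts can give). The difference of aerobic replicate 2 from 1 gave r of -0.23 (permutation p = 0.167) and that of anaerobic replicate 3 from 2 gave 0.20 (permutation p = 0.0667). Within a group the sign depends on which array is subtracted from which. Over the 6 differences within groups, none of these permutation p-values passed after adjustment by Benjamini-Hochberg (lowest adjusted permutation p = 0.1). With a smallest p of 0.0333, most of the 6 would have to reach that limit for any to pass. This therefore does not show that the wave is absent within groups.

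Likeness of neighbours with no broader order is argued against, since the highest amplitude in 10000 shuffles of blocks of 20 consecutive numbers was 0.29 (one-sided permutation p = 0.0001, the smallest they can give). Length, signal level and probe gradient do not account for the wave, whose amplitude was 0.40 after regression on these 3 measures, nor does the place on the chip, since the spots of each quadrant alone gave 0.38. An effect of the array run stays open, as it goes with the group. If the numbers follow the genome, a difference in gene copies along the chromosome or large regions regulated together may give such an order, but no positions were used and neither was tested.

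The gradient from the first to the last probes of a feature is another pattern. It differed between the groups by -0.21, and by -0.28 among features of middling signal level, where the arrays of the groups did not overlap either; this argues against compression of bright or dim signals. The difference was larger in longer features (Spearman rho -0.20 across features, bootstrap SE 0.02), with medians of -0.11, -0.25, -0.31 and -0.31 in 4 groups from the shortest to the longest features. Breakage of the RNA, or copying that stops early in 1 group, may give this, but so could any effect that grows with the distance between probes. A difference in how the cultures' own transcripts end was not tested, and the array run goes with the group.

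Background-subtracted signals of gene spots differed between the groups (anaerobic minus aerobic) by -1.92 on the log2 scale at the 10th percentile and by -0.71 at the 75th.

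Short features were less often lower in the anaerobic cultures than the others. Among the 371 features whose last probe starts nearest to the beginning (position 46 to 427), 19 were at least 2-fold lower (5.12%), against 132 among the other features (11.9%; odds ratio 0.40; Fisher's exact test across features, which are not independent, two-sided p = 0.0001). At least 2-fold higher were 54 short features (14.6%) and 124 of the others (11.2%), a difference that did not pass (odds ratio 1.36; Fisher's exact two-sided p = 0.0965). The balance of higher to lower calls differed by an odds ratio of 3.02 (Fisher's exact two-sided p = 0.0001). Its size depended on the scaling. With median scaling the odds ratio was 1.64 (Fisher's exact p = 0.0366), with the authors' deposited values 3.28 (Fisher's exact p = 4.8e-06), and with these centred on the median 3.69 (Fisher's exact p = 1.5e-07). Scaled to random-sequence spots, 8 short features were higher and 169 lower, against 24 and 545, and the difference no longer passed (odds ratio 1.07, Fisher's exact p = 0.833). At a 4-fold limit, with 7 short features each way against 16 higher and 25 lower, it did not pass either (odds ratio 1.55, Fisher's exact p = 0.539). The counts were 62 and 21 against 155 and 115 with the first 10 probes, and 47 and 25 against 100 and 164 with the last 10.

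Among the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave 1186 features past the test and 329 at least 2-fold changed. The highest of the other splits gave 0 in both counts. Every other split mixed arrays of the 2 groups, so the difference between the groups entered the spread within each side. This alone lowers the counts, so the 0 says nothing about chance or the array run. With 10 splits no share under 0.05 can be reached.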
